A study of Mus musculus with 3 samples.

How the data were processed

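The study measured RNA of N1E-115 cells, a mouse neuroblastoma line, on 3 spotted arrays with 2 colours. Per the labels, the Alexa555 channel held RNA of cells transfected with a plasmid for EGFP alone, and the Alexa647 channel held RNA of cells transfected with EGFP fused to 229 amino acids of the C-terminus of the mouse sodium channel NaV1.2. The fusion is called NaV1.2CT here. Cells were transfected 24 h after plating with 2 µg of plasmid, RNA was taken 48 h after transfection, and 10 µg of RNA was labelled. RNA of 3 dishes was pooled. The labels put 1 array at 5 mM glucose (low glucose) and 2 arrays at 20 mM glucose (high glucose). The growth protocol names a low-glucose medium for every sample, so the glucose levels rest on the sample labels alone. The series text says that the experiment was repeated at 20 mM, but nothing says that the arrays came from separate cultures, so p-values measure only the spread between these arrays.

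Each array had 23232 spots in 48 print blocks, of which 1235 were empty and 231 were GAPDH controls. Per the file headers, the deposited raw intensity and background intensity are mean values per spot and channel. The deposited net intensity of the EGFP channel equals raw minus background, with negative differences set to 0. The deposited net intensity of the NaV1.2CT channel was also multiplied by a factor that differs between spots, with a median of 1.23 on the low glucose array and 1.24 on each high glucose array. The deposited ratio divides EGFP by NaV1.2CT net intensity, which is the opposite direction to that used here. The deposited score is a z-score that is positive where NaV1.2CT was brighter. Its Spearman correlation across spots with the log2 ratio of the deposited net intensities was 0.864 on the low glucose array, 0.868 on high glucose replicate 1 and 0.789 on replicate 2. No z-score was given for 454, 918 and 8819 spots, in that order. How the authors made the score and the factor is not given in the sources used here, and neither are the scanner and the quantification software.

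Raw and background intensities of both channels were corrected with limma's normexp method at an offset of 50. Log2 ratios of NaV1.2CT over EGFP were then normalized by loess within each print block, with empty spots at weight 0. Loess over the whole array was replaced by loess per print block after the data were seen. With loess over the whole array, the print block explained 52.4% of the log ratio variance on the low glucose array and 54.1% and 40.4% on the high glucose arrays. After loess per print block it explained 0.204%, 0.132% and 0.103%, and in log ratios of the authors' net intensities 0.357%, 0.156% and 0.186%. Spots of the same accession and description were averaged, so 21766 gene spots became 21761 probes. Control and empty spots were left out of the tests. Probes were not filtered on intensity, and different probes of a gene were kept apart.

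A probe counted as above the empty limit on an array when raw minus background intensity in both channels was over the 95th percentile of that value in the empty spots. A is the mean log2 intensity of both channels. Gene names came from the symbols in the files, updated through a table of mouse genes of the assembly GRCm38.p6 that was used for names only. Of the 21761 probes, 14215 matched a current symbol, 2117 an older symbol and 96 an accession. A further 2150 kept the file's symbol, and 3183 had no gene name. The names covered 17185 genes.

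limma 3.58.1 in R 4.3.3 fitted each comparison with lmFit and eBayes, with Benjamini-Hochberg adjustment over all probes and a threshold of 0.05 on the adjusted p, two-sided. The first comparison set the mean log ratio of the 2 high glucose arrays against 0. The second set the mean of all 3 arrays against 0. The third subtracted the mean log ratio of the high glucose arrays from that of the low glucose array, which assumes that the lone low glucose array varies like the others. The residual degrees of freedom were 1, 2 and 1, and the prior added 7.54, 7.16 and 7.54. The low glucose array alone has no test. Every array had the same dye orientation, so an effect of a dye on a probe cannot be separated from the plasmid. The deposited files number the low glucose array in another series of arrays than the high glucose arrays, so array series and glucose cannot be told apart.

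A print group is taken here as the same 8 neighbouring positions in all 48 print blocks, from the spacing of the GAPDH control spots. Print groups with under 50% of their gene spots above the empty limit on all arrays are called print groups with little signal here. There were 23 gene lists, with 1 probe per gene, the one of highest intensity. limma's camera tested whether a list shifted against the other genes, with a preset correlation of 0.01 between genes and adjustment over the lists. A correlation estimated per list was run beside it, and limma's fry, which tests a list against no change rather than against other genes. On the low glucose array, each list's median was placed among 10000 random lists of the same size and similar intensity. The genes named for each comparison were the 10 highest and the 10 lowest mean log ratios among named probes that passed with the same sign on every array. Where fewer than 10 passed, the rest were filled by value with no claim of change. All sodium channel genes were named as well, with up to 4 members of each list by size. Names outside this rule are marked as chosen after their values were seen. The values of 1 list member are not reported here. Samples, comparisons, tests, lists, the rule for names and the first set of other settings were fixed before the data were examined.

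The first set of other settings held plain background subtraction, median centring, the authors' ratios, net intensities and scores, filters on dim probes, other priors, spots kept apart, other thresholds and each array left out. Alternatives added after the data were seen were loess over the whole array, removal of the median of neighbouring spots, a second loess of the log ratio over intensity with a span of 0.05, removal of print groups with little signal, and plain subtraction joined to the dim filter.

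The fits were tested on simulated data for 21761 probes, of which 67 were changed by 0.25, 67 by 0.5 and 66 by 1. In the high glucose design, 68.7% of the probes changed by 0.25 on the log2 scale were recovered, and 100% at 0.5 and at 1. In the design of 3 arrays, 86.6%, 95.5% and 100% were recovered. In the glucose difference design, 1.49%, 80.6% and 97.0% were recovered. Among unchanged probes, 17, 0 and 17 were called in those designs. A list shifted by 0.1 was found in both designs that test lists, with 0 other lists called. The simulation holds an offset per print block and a slope of the log ratio over intensity, but no dye effect and no effect of position within a block. Files were read with the R packages data.table, version 1.17.8, and jsonlite, version 2.0.0, and figures were drawn with matplotlib 3.10.9 in Python 3.11.15.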

Results

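The series compared cells that carried NaV1.2CT, the C-terminus of a neuronal sodium channel fused to EGFP, with cells that carried EGFP alone. The channel's full protein is encoded by Scn2a. Each array held both RNAs, so each log2 ratio is NaV1.2CT over EGFP. The low glucose group (5 mM) had 1 array and the high glucose group (20 mM) had 2 arrays. Median raw intensity in the EGFP channel was 1706 on the low glucose array, 1172 on high glucose replicate 1 and 1106 on replicate 2, and in the NaV1.2CT channel it was 1355, 946 and 890. Median local background lay between 44.7 and 54.3. Of 21761 probes, 92.0%, 92.4% and 91.5% were above the empty limit in both channels. The SD of the log2 ratio across probes was only 0.10 on the low glucose array, 0.10 on high glucose replicate 1 and 0.11 on replicate 2. The number of arrays limits the precision.

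Spots are given by the gene names in the files, and brightness followed those names only weakly. The 75 cytosolic ribosomal protein genes, which nearly all cells express strongly, had a median brightness at percentile 52.2. Percentiles here rank the brightest probe of each named gene, outside print groups with little signal. The olfactory and vomeronasal receptor genes, which such cells are not expected to express, lay lower, with 183 of them outside print groups with little signal and a median at percentile 20.2. Yet 144 of the 184 genes of this list were above the empty limit on every array. A probe above that limit therefore does not show that the named transcript was present. Different probes of a gene had a Spearman correlation of brightness of 0.067 over 887 pairs. Each gene below therefore stands for the spot of that name. Log ratios also moved with intensity after normalization, up at the bright end, with smaller moves among dim probes and a dip between an A of 13 and 14. In that dip the median was -0.0204 on the low glucose array, -0.0252 on high glucose replicate 1 and -0.0215 on replicate 2. There 40.5%, 36.8% and 41.8% of probes were above 0. Above an A of 15, the median log2 ratio was 0.13 on the low glucose array, 0.14 on high glucose replicate 1 and 0.14 on replicate 2, with 84.7%, 91.2% and 86.7% of probes above 0. Between an A of 7 and 8 it was -0.07 on the low glucose array, with 26% of probes above 0, and -0.06 on high glucose replicate 1, with 31.7%, but 0.0064 on replicate 2. Below an A of 7 it was 0.02 on the low glucose array, with 64.1% above 0, and 0.01 on high glucose replicate 1, with 57.4%.

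**Figure D1:**
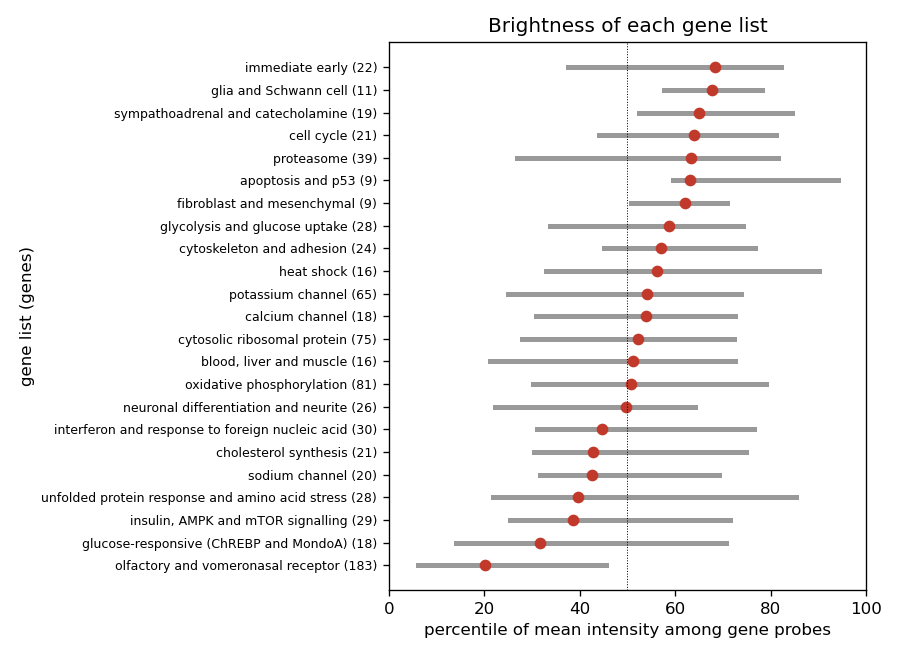
Brightness of each gene list: the x axis is the percentile of mean intensity among gene probes, points are list medians and bars run from the 25th to the 75th percentile of the list, with the number of genes outside the print groups with little signal in brackets. The olfactory and vomeronasal receptor list has the lowest median, at percentile 20.2, and the cytosolic ribosomal protein list lies at 52.2.

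The first comparison asked how NaV1.2CT changed transcripts at 20 mM glucose. The largest increases were at 2 single spots, a probe of the 18S ribosomal RNA gene Rn18s and the small subunit protein gene Rps16. Spots named Ska2, part of the complex that ties chromosomes to the spindle, and Phlda1, a gene tied to cell death, also rose. Among spots with signal in both channels, the largest decrease was at the noncoding RNA gene Redrum. No sodium channel gene passed the test. The only Scn2a probe, whose description in the files names the 3' end of an mRNA, had a log2 ratio of 0.12. This value gives no sign of the transfected sequence. The description does not give the position of the probe, and whether it covers the fused C-terminus was not analysed here. The spots that rose are in the bright range where most log ratios were above 0. The NaV1.2CT channel reached the scanner limit of 65535 at 3 gene spots of high glucose replicate 1 and 2 of replicate 2, and the EGFP channel at none. Whether the spots named here are among them was not analysed.

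In the high glucose comparison, 459 probes passed limma's test after adjustment, 150 higher and 309 lower with NaV1.2CT, each in the same direction on 2 of 2 arrays. At an unadjusted p of 0.05, 4828 probes passed, where 1088 would pass by chance. The median size of the passing changes was 0.25 on the log2 scale, the largest was 0.63, and 0 reached 1. The split of higher and lower probes moved with the scaling. It was 4012 to 4088 with median centring, 3268 to 4380 with loess over the whole array and 31 to 40 with the ratios as the files give them, but 18 to 61 with loess on the authors' net intensities and 10 to 28 with plain background subtraction. Of the higher probes, 50% had an A above 14, against 5.39% of all probes. Of the lower probes, 56.6% had an A under 9, against 29.0% of all probes. After a second loess over intensity, chosen after the data were seen, 855 probes passed, and 117 of the 150 higher and 307 of the 309 lower probes were still among them.

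**Figure D2:**
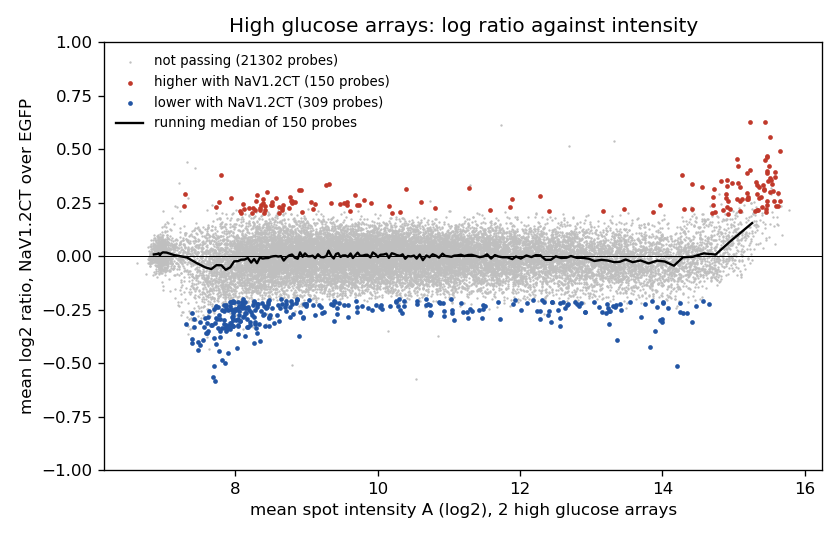
Mean log2 ratio of NaV1.2CT over EGFP against mean log2 intensity A for the 2 high glucose arrays, with a point per probe (150 higher, 309 lower and 21302 not passing) and a running median of 150 probes. The running median rises above an A of 15, and 1 probe lies outside the plotted range.

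Rn18s rose by 0.63 (SD 0.16, n = 2, limma adjusted p 0.00673) and Rps16 by 0.63 (SD 0.13, adjusted p 0.00614), both higher on 2 of 2 arrays. The second Rn18s probe, at 0.11 and 0.47 on the high glucose arrays, did not pass (adjusted p 0.0795). Ska2 rose by 0.49 (SD 0.0017, adjusted p 0.00614) and Phlda1 by 0.46 (SD 0.073, adjusted p 0.00931), also on 2 of 2 arrays. The testis transcripts 1700128I11Rik, 1700013D24Rik and 4930563M21Rik rose by 0.47, 0.46 and 0.45. Ccdc71 rose by 0.42, Pgm2l1, which encodes a sugar bisphosphate synthase, by 0.40 and Lrr1 by 0.40, with adjusted p from 0.0129 to 0.0173. After the second loess over intensity all 10 still passed, with smaller values such as 0.51 for Rn18s, 0.46 for Rps16 and 0.37 for Phlda1. Pgm2l1 did not pass with loess over the whole array, where its adjusted p was 0.0573. With plain background subtraction only 3 of the 40 passing probes named for high glucose still passed, and none of these 10 was among them.

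Redrum, a long noncoding RNA gene first described in red cells, fell by 0.52 (SD 0.029, n = 2, limma adjusted p 0.00614, lower on 2 of 2 arrays). Cyp4f16, a cytochrome P450 gene, fell by 0.43 (SD 0.042, adjusted p 0.00931) and 6430628N08Rik by 0.45 (SD 0.0032, adjusted p 0.00673). Asic2, an acid-sensing channel of the sodium channel superfamily, fell by 0.50 and Cep19, a cilium gene, by 0.48, but each was above the empty limit on only 1 of 2 arrays. Gabpb1, Hmg20b, Rnf122, Aqp7 and Lilrb4a also fell, and none of their probes was above the empty limit in both channels on a high glucose array, so no size is given. A further 4 spots were chosen after their values were seen, each lower on 2 of 2 arrays. Gem, a small GTPase that restrains calcium channels, was at -0.38 (adjusted p 0.0173). Its spot was the dimmest of the 4, with an A of 8.75 and 9.02 on the high glucose arrays. Brighter were the cohesin gene Esco2 at -0.39 (0.0173), the kinase Melk at -0.32 (0.0197) and Hoxb5, a neural crest gene, at -0.31 (0.026). With median centring Redrum, Esco2, Melk and Hoxb5 did not pass, with log2 ratios of -0.05, -0.10, -0.04 and -0.09.

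Channel genes were mostly without a passing change at 20 mM glucose. Of 23 sodium channel and partner genes, 0 rose, 1 fell and 22 did not pass (0 rose and 1 fell adjusted over the list alone). Scn2a had a limma adjusted p of 0.143 and passed with loess over the whole array, at 0.22 (adjusted p 0.00202). Among the other sodium channel genes, log2 ratios ran from -0.12 for Scn10a to 0.10 for Scn8a. Of 66 potassium channel genes, 0 rose, 1 fell and 65 did not pass, and 7 fell adjusted over the list alone. Kcne2, an accessory subunit, fell by 0.28 (SD 0.0012, adjusted p 0.0252, lower on 2 of 2 arrays). The potassium channel list as a whole lay lower (camera adjusted p 0.0343, median -0.04, 21 of 66 genes above 0). Its adjusted p was 0.891 when the correlation was estimated, a setting in which no list had a lower value. fry, which asks whether a list changed at all and not against other genes, gave the potassium channel list an adjusted p of 0.401. Of 20 calcium channel genes, 0 passed, 2 fell adjusted over the list alone (camera adjusted p 0.0886, median -0.06, and adjusted p 0.0484 without probes below the 25th percentile of intensity), and Cacnb1 passed after the second loess, at -0.18. The correlation estimated for the calcium channel list was 0.116, above the preset 0.01, and the camera adjusted p was then 0.891. The neuronal differentiation list had the same adjusted p at an estimated correlation of -0.032, so correlation alone does not account for this value.

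Neuronal and metabolic genes changed at single spots. Of 20 sympathoadrenal genes, 0 rose and 1 fell (2 rose and 4 fell adjusted over the list alone), and 0 of 28 neuronal differentiation genes passed (0 and 0 over the list alone). The noradrenaline transporter Slc6a2 fell by 0.23 (limma adjusted p 0.039, lower on 2 of 2 arrays) and did not pass with median centring (-0.11, adjusted p 0.205). Of 28 glycolysis genes, 1 rose and 1 fell (1 and 1 over the list alone). These were the lactate exporter Slc16a3 at 0.21 (adjusted p 0.0458) and the glycolytic regulator Pfkfb3 at -0.27 (0.0457), each in its direction on 2 of 2 arrays. The insulin receptor Insr fell by 0.26 (adjusted p 0.0295, 2 of 2 arrays), as the only 1 of 30 insulin, AMPK and mTOR genes to pass (0 rose and 1 fell over the list alone). Of 87 oxidative phosphorylation genes, Ndufa12 rose by 0.34 (0.0231) and the testis isoform Cox7b2, above the empty limit on 2 of 3 arrays in all, fell by 0.30 (0.0484) (1 and 1 over the list alone). Of 18 glucose-responsive genes 0 passed (0 over the list alone), and of 21 cholesterol synthesis genes 0 passed (2 fell over the list alone).

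Genes of protein handling and growth at 20 mM glucose followed. Of 75 cytosolic ribosomal protein genes, 2 rose, 0 fell and 73 did not pass (2 and 0 adjusted over the list alone), namely Rps16 and Rpl36a at 0.22 (limma adjusted p 0.0457, higher on 2 of 2 arrays), which did not pass with median centring (0.01, adjusted p 0.891). The list as a whole did not pass (camera adjusted p 0.411). The endoplasmic reticulum chaperone Hspa5 rose by 0.27 (adjusted p 0.0373), as 1 of 28 unfolded protein response genes (1 and 0 over the list alone). Of 42 proteasome genes 0 passed (0 over the list alone), and of 17 heat shock genes 0 passed (1 fell over the list alone). Of 44 cell cycle genes, 0 passed (0 over the list alone), yet the list lay higher (camera adjusted p 0.0215, median 0.04, 35 of 44 genes above 0). Its adjusted p was 0.891 with the correlation estimated, where no list had a lower value. The adjusted p was 0.221 without 23 genes in print groups with little signal, where the median of the 21 genes left was still 0.04. All 1140 probes of those print groups had a median of 0.0149, against -0.0044 for other probes. Of 31 apoptosis and p53 genes 0 passed (0 over the list alone). The interferon-induced gene Ifit1, above the empty limit on 2 of 3 arrays in all, fell by 0.28 (adjusted p 0.0295), as 1 of 31 interferon genes (0 rose and 1 fell over the list alone). Klf2 rose by 0.27 (0.0292) among 24 immediate early genes (3 rose and 4 fell over the list alone), and the adhesion gene Tln1 by 0.24 (0.0458) among 27 cytoskeleton genes (1 and 0 over the list alone). All of these directions held on 2 of 2 arrays. Ndufa12, Hspa5, Klf2 and Tln1 are bright spots and did not pass after the second loess, at 0.15, 0.17, 0.12 and 0.04.

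Lists for other cell types were tested at 20 mM glucose as well. They could show foreign RNA only where it differed between the channels, since RNA present alike in both gives a log ratio near 0. Of 15 fibroblast genes, 1 rose and 0 fell (1 and 0 adjusted over the list alone), which was Col6a1 at 0.23 (limma adjusted p 0.0418, higher on 2 of 2 arrays) in a print group with little signal. Of 12 glial genes 0 passed (1 rose over the list alone), and of 17 blood, liver and muscle genes 0 passed (0 over the list alone). Of 184 olfactory and vomeronasal receptor genes, 2 rose and 2 fell (3 and 3 over the list alone), among them Olfr870 at 0.25 (adjusted p 0.0297) and Vmn2r-ps54 at -0.25 (0.0328). These cells are not expected to express this family, yet its share of passing genes was close to that of all probes (459 of 21761). No other list passed in camera, with adjusted p up to 0.968. fry called 0 lists for a shift one way, and 2 when changes of either direction counted. Median and camera direction differed in sign for the sympathoadrenal, unfolded protein response, cytoskeleton and blood, liver and muscle lists, and median and mean for the glucose-responsive, cytoskeleton and olfactory lists.

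The second comparison asked which changes with NaV1.2CT were shared by the 3 arrays of both glucose levels. Rps16, Rn18s, Ska2 and Phlda1 again rose and Redrum again fell, each on 3 of 3 arrays. Ptgfrn, a membrane protein gene of the tetraspanin web, and Naip6, an inhibitor of apoptosis gene, joined the largest increases. Among genes of the nervous system, the neurofilament gene Nefm and the homeobox gene Isl1 rose, while Eno2, the neuronal enolase, and Slc6a2 fell. Nefm did not pass after the second loess, and Eno2 turned direction with median centring. Potassium channel genes Kcne2, Kcnj1 and Kcnd2 fell. These 3 of 66 are a share close to that of all probes (837 of 21761).

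Across the 3 arrays, 837 probes passed limma's test after adjustment, 254 higher and 583 lower, each in the same direction on 3 of 3 arrays. Of these, 317 had also passed in the high glucose comparison, which shares 2 of the 3 arrays, so the overlap is not independent. The split was 4280 to 4502 with median centring, 0 to 4 with the ratios as the files give them, 0 to 2 with plain background subtraction and 0 to 1 with loess on the authors' net intensities. At an unadjusted p of 0.05, 5217 probes passed, where 1088 would by chance. The median size of passing changes was 0.20, the largest at a probe above the empty limit on every array was 0.55, and 0 reached 1. Of the higher probes, 46.5% had an A above 14, against 5.84% of all probes. After the second loess over intensity 581 passed, which kept 160 of the higher and 370 of the lower probes. Of the 298 lower probes with an A under 9, which are 51.1% of the lower probes, it kept 175. With 1 array left out, 459 passed without the low glucose array, 471 without high glucose replicate 1 and 757 without replicate 2.

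**Figure D3:**
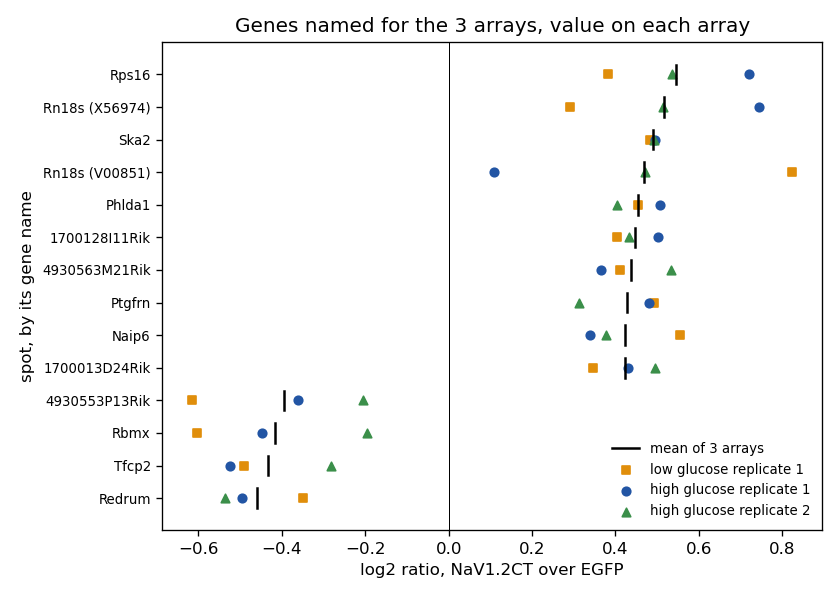
Log2 ratio of NaV1.2CT over EGFP on each of the 3 arrays (points) and their mean (black bars) for the genes named by rule in the comparison of 3 arrays whose probes were above the empty limit on at least 2 arrays. Rps16 has the highest mean, 0.55, and Redrum the lowest, -0.46.

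Rps16 rose by 0.55 (SD 0.17, n = 3, limma adjusted p 0.00664), Rn18s by 0.52 (SD 0.23, 0.0133) and Ska2 by 0.49 (SD 0.0065, 0.00259), each on 3 of 3 arrays. The second Rn18s probe rose by 0.47 with a wide spread (SD 0.36, adjusted p 0.0435), and did not pass after the second loess (0.29, adjusted p 0.136). With plain background subtraction only 1 of the 51 passing probes named for the 3 arrays still passed, Hmg20b. With 1 array left out, 35 passed without the low glucose array, 37 without high glucose replicate 1 and 40 without replicate 2. Phlda1 rose by 0.45, 1700128I11Rik by 0.45, 4930563M21Rik by 0.44, Ptgfrn by 0.43, Naip6 by 0.42 and 1700013D24Rik by 0.42, with adjusted p from 0.00371 to 0.00754. Redrum fell by 0.46 (SD 0.098, adjusted p 0.00484) and the transcription factor gene Tfcp2 by 0.43 (SD 0.13, 0.0086), each on 3 of 3 arrays. The RNA-binding protein gene Rbmx fell by 0.42 (adjusted p 0.02) and 4930553P13Rik by 0.39 (0.0228), both above the empty limit on 2 of 3 arrays. Hmg20b, Gabpb1, Lilrb4a, Rnf122, Aqp7 and Mindy3 fell as well, at probes above the empty limit in both channels on no more than 1 array, so no size is given. Chosen after their values were seen, Cyp4f16 at -0.39 (0.00627), Esco2 at -0.31 (0.0231), Hoxb5 at -0.30 (0.0114) and Melk at -0.28 (0.0146) were lower on 3 of 3 arrays. With median centring Redrum, Esco2 and Hoxb5 did not pass, and Melk was at 0.07.

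Of 23 sodium channel and partner genes, 0 rose, 1 fell and 22 did not pass over the 3 arrays (0 and 1 adjusted over the list alone). Scn2a was at 0.11 (SD 0.022, n = 3, limma adjusted p 0.105), higher on 3 of 3 arrays but not passing. Scn2a passed with median centring (0.14, adjusted p 0.0325) and with loess over the whole array (0.21, adjusted p 0.00265). Of 66 potassium channel genes, 0 rose, 3 fell and 63 did not pass (7 fell over the list alone), with Kcne2 at -0.21 (0.0398), Kcnj1 at -0.21 (0.0295) and Kcnd2, a channel of the A-type current, at -0.18 (0.0331), each lower on 3 of 3 arrays. The potassium channel list did not pass (camera adjusted p 0.0784, median -0.05), and neither did the calcium channel list (0.195), where 0 of 20 genes passed (0 over the list alone).

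Among neuronal genes over the 3 arrays, 1 of 28 differentiation genes rose and 1 fell (3 and 1 adjusted over the list alone), which were Nefm at 0.16 (limma adjusted p 0.0461) and Eno2 at -0.18 (0.0343). Of 20 sympathoadrenal genes 1 rose and 1 fell (2 and 3 over the list alone), Isl1 at 0.18 (0.042) and Slc6a2 at -0.23 (0.0187), each in its direction on 3 of 3 arrays. Nefm did not pass after the second loess (adjusted p 0.067). Eno2 turned to 0.18 with median centring. Of 44 cell cycle genes, 2 rose and 0 fell (2 and 0 over the list alone), Plk1, a mitotic kinase, at 0.16 (0.0428) and Cdc45, a replication gene in a print group with little signal, at 0.17 (0.0443). The cell cycle list lay higher (camera adjusted p 0.00163, median 0.04, 35 of 44 genes above 0). With the correlation estimated its adjusted p was 0.752. That correlation was -0.0025, below the preset 0.01, so correlation does not explain the loss. The setting tests on only 2 residual degrees of freedom, so its value cannot tell whether the list shifted. Without the print groups with little signal the adjusted p was 0.195, and the median of the 21 genes left was 0.03. All 1140 probes of those print groups had a median of 0.021 over the 3 arrays, against -0.0064 for other probes. Of 31 apoptosis genes 0 passed (0 over the list alone).

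For metabolism over the 3 arrays, Slc16a3 rose by 0.17 (limma adjusted p 0.0462) and Pfkfb3 fell by 0.28 (0.0201) among 28 glycolysis genes (1 and 1 adjusted over the list alone). Ndufa12 rose by 0.27 (0.0289) and Cox7b2 fell by 0.31 (0.0201) among 87 oxidative phosphorylation genes (1 and 1 over the list alone). Of 18 glucose-responsive genes 1 fell (1 over the list alone), the citrate lyase gene Acly, whose probe was not above the empty limit on any array. The squalene epoxidase gene Sqle fell by 0.21 (0.0361) among 21 cholesterol genes (2 fell over the list alone), and 0 of 30 insulin, AMPK and mTOR genes passed (0 over the list alone). Each of these directions held on 3 of 3 arrays. Slc16a3, Ndufa12 and Sqle did not pass after the second loess, with adjusted p of 0.0505, 0.26 and 0.0605.

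For protein handling and stress over the 3 arrays, Rps16 and Rpl36a (0.19, limma adjusted p 0.0325) rose among 75 cytosolic ribosomal protein genes, with 0 falling (3 rose adjusted over the list alone). Rpl36a was at -0.0071 with median centring. Of 42 proteasome genes, 1 rose and 1 fell (3 and 2 over the list alone), Psmb3 at -0.17 (0.0411) and Psme3ip1 at 0.18 (0.0343), which is not a proteasome subunit but has a name that the list's pattern takes. Hspa5 rose by 0.25 (0.0194) and Trib3, a stress-induced pseudokinase, fell by 0.16 (0.0494) among 28 unfolded protein response genes (1 and 3 over the list alone). The chaperonin gene Hspe1 fell by 0.17 (0.0371) among 17 heat shock genes (1 rose and 3 fell over the list alone), and Egr2 by 0.19 (0.0484) among 24 immediate early genes (1 and 2 over the list alone). fry called both of those lists lower (adjusted p 0.0444 for each) and 0 lists higher, while camera did not call them. When changes of either direction counted, fry called 21 of the 23 lists, among them the olfactory and vomeronasal receptor list (adjusted p 0.00709). Ifit1 fell by 0.32 (0.0124) among 31 interferon genes (1 fell over the list alone), and Tln1 rose by 0.24 (0.0206) among 27 cytoskeleton genes (2 and 1 over the list alone). All these directions held on 3 of 3 arrays, and Hspa5, Trib3, Egr2 and Tln1 did not pass after the second loess, with adjusted p of 0.0791, 0.0537, 0.0583 and 0.392.

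In the lists of other cell types over the 3 arrays, 0 of 12 glial, 0 of 15 fibroblast and 0 of 17 blood, liver and muscle genes passed, with 0 adjusted over the list alone in each. Of 184 olfactory and vomeronasal receptor genes, 3 rose and 9 fell (6 and 18 over the list alone), among them Vmn2r-ps54 at -0.26 (limma adjusted p 0.0133, lower on 3 of 3 arrays). That is a larger share than of all probes (837 of 21761), in a family these cells are not expected to express. Vmn1r11 also fell, at a probe not above the empty limit on any array. The lists other than the cell cycle list did not pass in camera, with adjusted p from 0.0784 for the potassium channel list to 0.977. Camera direction and mean differed in sign for the sympathoadrenal, glycolysis, unfolded protein response and blood, liver and muscle lists, and camera direction and median for the insulin and unfolded protein response lists.

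On the low glucose array alone, with no replicate and so no test, 0 probes reached a log2 ratio of 1 in size. A ratio of 1.5-fold was reached by 15 probes, 7 higher and 8 lower, of which 2 were above the empty limit. The highest values above the dim filter were 0.82 for the second Rn18s probe, which was at 0.11 and 0.47 on the high glucose arrays, 0.56 for Naip6, 0.50 for 1010001I08Rik, 0.50 for the splicing factor gene Rbm17 and 0.49 for Ptgfrn. The lowest were -0.54 for Tfpi2, an inhibitor of proteases, -0.50 for 4930515L03Rik, -0.46 for the catenin gene Ctnnd1, -0.41 for 5730433N10Rik and -0.40 for Enpp3. The cell cycle list had a median of 0.05, at percentile 99.9 of random lists, and the unfolded protein response list 0.03, at percentile 96.6. Of the 44 cell cycle genes, 23 lie in print groups with little signal. The olfactory and vomeronasal receptor list had a median of -0.06, at percentile 0, the heat shock list -0.06, at 4.08, and the glucose-responsive list -0.05, at 8.35. The other lists lay between percentile 19.7 for the interferon list and 98.8 for the oxidative phosphorylation list.

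The third comparison asked whether the change with NaV1.2CT differed between 5 mM and 20 mM glucose. Only 6 probes passed limma's test, 4 with a higher and 2 with a lower ratio on the low glucose array, and none lay in a gene list. The 4 named spots were Cth, an enzyme that makes cysteine, the ubiquitin ligase gene Trim25, 6230426I18Rik and Phactr3, a phosphatase regulator. Cth, Trim25 and 6230426I18Rik were not above the empty limit on the low glucose array and Phactr3 on no array, so no size is given. The 1 probe above the empty limit on every array has no gene name. It was at -0.51 on the low glucose array and at 0.31 and 0.32 on the high glucose arrays (difference -0.83, adjusted p 0.0188). At an unadjusted p of 0.05, 1632 probes passed, where 1088 would by chance. The split of 4 to 2 became 13 to 23 with the ratios as the files give them, 14 to 14 with loess on the authors' net intensities, 16 to 25 with loess over the whole array and 10 to 12 after the second loess. It was 10 to 13 with plain background subtraction, 9 to 11 with the authors' z-scores and 6 to 9 with the median of neighbouring spots removed. It was 101 to 64 with median centring, but 0 to 6 without probes below the 25th percentile of intensity and 0 to 5 without those below the median, which share only 1 and 0 probes with the 6. In the 23 lists, 0 genes passed, while 1 insulin, AMPK and mTOR gene, 1 proteasome gene and 1 olfactory receptor gene were higher at low glucose adjusted over the list alone. Among spots that did not pass, Tex2 was at -0.29 on the low glucose array and 0.34 and 0.30 on the high glucose arrays (adjusted p 0.05), and Tfpi2 at -0.54 against 0.22 and 0.01 (adjusted p 0.109).

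Log ratios were compared between arrays across the 21761 probes, which are not independent replicates. The high glucose arrays had a Pearson correlation of 0.484 (Spearman 0.501). The low glucose array correlated at 0.458 (0.437) with high glucose replicate 1 and at 0.321 (0.322) with replicate 2. A z-score of 2 in size with the same sign was found on both high glucose arrays for 229 probes, where independent lists give 22.7, and opposite signs for 2. For the low glucose array it was 244 with high glucose replicate 1 (26.8 from independent lists) and 134 with replicate 2 (22.9).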

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

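The comparison of glucose levels and the count of dye orientations were planned, and the other tests in this part were chosen only after the result was seen, some in place of earlier ones.

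A difference between groups was marked because 6 probes passed limma's test of the glucose difference. The single low glucose array came from another series of arrays, and 4 of the 6 probes differed in brightness by over 2 log2 units between glucose levels, against 5.23% of probes. The probe with the largest difference, which has no gene name (-0.83, adjusted p 0.0188), was above the empty limit on every array and differed in brightness by only -0.0354.

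A signal in spots outside the comparisons was marked because log ratios of 216 GAPDH control spots correlated at 0.54 between the high glucose arrays, against 0.411 for 298 other gene spots of the same blocks and brightness. The correlation was 0.28 between the low glucose array and high glucose replicate 1 (0.502 for the other spots), and 0.38 with replicate 2 (0.321).

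Log ratios correlated between arrays, and position, dye and a transcript change were weighed. GAPDH control spots hold the same sequence, and their covariance between the high glucose arrays was 0.42 (95% interval 0.252 to 0.748) times that of other gene spots of the same blocks and brightness, so position alone does not account for all of the covariance, although the higher GAPDH correlation of 0.54 leaves room for a part of it. With 1 dye orientation in the design, a dye effect particular to each probe could give the same pattern and cannot be told apart from the plasmid. A transcript change should be shared by different probes of a gene, and their mean log ratios had a Spearman correlation of 0.0015 over 581 bright pairs. That value cannot tell either way where brightness of sibling probes is itself hardly related.

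Brightness followed the gene names only weakly, and a random placing of names and differences between probes were weighed. Olfactory and vomeronasal receptor spots had a median brightness percentile within their print groups of 34.7 (95% interval 28.8 to 40.4), where names placed at random would give about 50. Names placed at random over the spots of each print group therefore do not account for the brightness of this list. Brightness of different probes of a gene had a Spearman correlation of 0.067, which is in line with brightness set more by the probe than by its gene, and could also come from names that are wrong for part of the spots. No biological explanation was tested.

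Probes higher with NaV1.2CT lay among the brightest spots, and a trend of log ratio with intensity left after loess per print block was weighed. Of 75 bright probes higher at high glucose, 42 still passed after a second loess over intensity, and the median log2 ratio of the 75 went from 0.30 (SD 0.094) to 0.18 (SD 0.099). The trend could account for those that were lost, and the 42 that stayed cannot be assigned to it or to a transcript change. No biological explanation was tested for the brightest spots as a group.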

How the results depend on the processing

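The alternatives with loess over the whole array, the median of neighbouring spots, the second loess, the print groups with little signal and plain subtraction joined to the dim filter were chosen only after the result was seen. The counts of calls depended strongly on scaling and background, and the cause was not tested unless it is given here.

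High glucose calls (459) became 38 with plain background subtraction, 8100 with median centring, 71 with the ratios as the files give them, 79 with loess on the authors' net intensities, 7648 with loess over the whole array, 733 with the median of neighbouring spots removed, 855 with the second loess and 741 with an intensity trend in eBayes. They became 1536 at an adjusted p of 0.1, 4828 at an unadjusted p of 0.05 and 0 with a log2 ratio of 1 required as well. Calls of the 3 arrays (837) became, in the order of those scalings, 2, 8782, 4, 1 and 7604, with 555 from the authors' z-scores and 463 without probes below the median intensity. They became 2289 at an adjusted p of 0.1, 5217 unadjusted and 0 with a log2 ratio of 1 required. With 1 array left out they ranged from 459 to 757, and removing the low glucose array (459) or high glucose replicate 1 (471) moved the count by over 1.5 times. With the sign of 1 array turned, 0 probes passed, both for high glucose replicate 2 in the high glucose comparison and for each of the 3 arrays in the second. Plain subtraction lost its calls through the dim probes, since 619 and 593 probes passed when it was joined to the filter at the 25th percentile of intensity.

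Glucose difference calls (6) became 23 with plain background subtraction, 165 with median centring, 36 with the files' ratios, 28 with the authors' net intensities, 20 with the z-scores, 41 with loess over the whole array, 15 with neighbouring spots, 22 with the second loess, 17 with an intensity trend and 15 with plain subtraction and the dim filter. Without probes below the 25th percentile of intensity 6 passed, and without those below the median 5, but these share only 1 and 0 with the 6 probes first called. The cause was not tested.

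Gene list shifts at high glucose (2) became 4 with the files' ratios. They became 1, the cell cycle list, with plain subtraction, net intensities and neighbouring spots. Without probes below the 25th percentile they also became 1, but this was the calcium channel list (adjusted p 0.0484), while potassium channels (0.0943) and cell cycle (0.549) were lost. With that filter the potassium channel median was -0.0441 over 57 genes, against -0.0449 over 66. The cell cycle median was 0.0268 over 18 genes, against 0.0396 over 44. The list shifts became 0 with median centring, z-scores, loess over the whole array, the second loess, without probes below the median intensity, without the print groups with little signal, with the correlation estimated and with fry. Medians of the potassium channel and cell cycle lists were -0.0705 and 0.0804 with median centring and -0.0513 and 0.0350 with loess over the whole array. They were -0.0413 and 0.0355 with the second loess, and -0.0197 and 0.0407 without probes below the median intensity. For the 3 arrays (1) the count was 2 with median centring and 2 with fry. It was 0 with z-scores, loess over the whole array, each dim filter, without the print groups with little signal and with the correlation estimated. In both comparisons the count of 0 with the correlation estimated cannot tell whether a list shifted, since few degrees of freedom remain there. With 1 array left out it ranged from 1 to 2, and was 2 without the low glucose array and without high glucose replicate 1.

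Low glucose ratios of at least 1 in size (0) became 63 with plain subtraction, 21 with median centring, 71 with the files' ratios and 65 with net intensities. There were 15 at 1.5-fold and 1007 with an authors' z-score of at least 2 in size.

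Probes that shared a direction between the high glucose arrays (229) became 637 and 33 at z-scores of 1.5 and 3, 0 at a log2 ratio of 1, 622 with median centring, 462 with loess over the whole array and 81 with the authors' z-scores. For the low glucose array and high glucose replicate 1 (244) these were 654, 55, 0, 532, 557 and 152, with 131 without dim probes. For the low glucose array and replicate 2 (134) they were 462, 21, 0, 485, 375 and 48. The cause was not tested.

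The direction turned for Aurkb at high glucose with loess over the whole array (-0.0162), and with median centring for Eno2 (0.18), Rpl36a (-0.0071) and Melk (0.0676) over the 3 arrays and for Enpp3 on the low glucose array (0.0479). The cause was not tested. The other named genes kept their direction with median centring, plain subtraction, loess over the whole array, the second loess and arrays left out, the only settings run per gene. With 1 array left out, the median size of passing changes at high glucose ranged from 0.24 to 0.26. The robust option of eBayes was not run for gene lists, since camera has none. No paired analysis was possible because the groups share fewer than 2 replicate numbers. Signal over background limits the dim probes. Of the lower probes, 262 of 309 at high glucose and 451 of 583 over the 3 arrays were above the empty limit on every array of the comparison.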

Other observations

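The tests in this part were chosen only after the result was seen.

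Of 58 print groups with gene spots, 3 held little signal, and of their 1140 probes 15.7% were above the empty limit on all arrays, against 93.8% elsewhere. Their 12 GAPDH control spots had a median A of 7.15, against 13.7 for the 219 elsewhere. The 3 groups differ, with 1.58%, 2.89% and 42.6% of gene spots above the limit, and the last had GAPDH control spots at a median A of 10.4. Of 44 cell cycle genes 23 lie in these groups, and of 31 apoptosis and p53 genes 22.

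Brightness of single spots varied widely under names of strongly expressed genes. The actin gene Actb lay at percentile 55.9 of brightness and Actg1 at 11.1, the ferritin gene Fth1 at 8.71, Ppia at 12.7 and the neuronal tubulin gene Tubb3 at 11.5. The liver gene Alb lay at 93.7 and the insulin gene Ins1 at 98.4, and the probes of Rn18s at 99.7 and 99.9. The control gene Gapdh lay at 80.4, the chaperone gene Hspa5 at 99.5, Th, which makes catecholamines, at 77.0, Rplp0 at 69.5 and Eef1a1 at 65.1. Hspa5, Rplp0 and Eef1a1 have 2 probes each, and only the brighter is given. These genes were chosen after their values were seen, and brightness of different probes does not compare levels of their transcripts.

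Of 1114 genes with over 1 probe, 6 had over 1 probe that passed in the comparison of 3 arrays, and 6 of the 6 moved the same way. Over 887 pairs of probes of a gene, 51.3% had the same sign, and of 581 bright pairs 49.7%. The noncoding transcript 4930422I22Rik had a log2 ratio of 1.14 on high glucose replicate 1, the only probe above the empty limit to reach 1 on any array.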
